A study of Mus musculus with 2 samples.

How the data were processed

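Chromatin immunoprecipitation sequencing (ChIP-seq) of dimethylated lysine 4 of histone H3 (H3K4me2), a mark of promoters and enhancers, was done on hindbrain of newborn mice at postnatal day 0. Per the labels, animals of both sexes were pooled, the samples form 1 group of 2 biological replicates, and replicate 1 was made from 15 mice. The number of mice behind replicate 2 is not given in the sources used here. Library fragments were selected at 300 to 500 bp, per the labels. The series has 1 group and no control condition among its samples, so no difference between conditions was tested.

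The authors deposited 4 peak lists on the mouse build mm10 (GRCm38): 1 list for each replicate, 1 called on both replicates pooled, and 1 replicated list. Per the file headers and notes that accompany the lists, the replicate and pooled lists were called from filtered alignments with a control alignment among the inputs, and the replicated list was derived from the other 3. The aligner, the peak caller, its version and its threshold are not given in the sources used here. Each peak carries the authors' deposited signal value, called enrichment here, and whether that value is a fold over the control is not given in the sources used here. The authors also deposited −log10 p and −log10 q values for each peak, and a display score that was not used here. Enrichment is the authors' own value for a peak. It served to describe, rank or filter peaks within a list, to correlate the replicates and to match random lists in the closing section. Ranks from lists of different lengths show no change. Sequencing depth is unknown because peak lists hold no read counts, so no floor of detection could be given.

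The rule behind the replicated list was tested on the lists themselves. All 36808 replicated peaks had the same coordinates as a pooled peak. A pooled peak overlapping a peak of each replicate over at least 50% of the length of either peak was kept in 33868 of 33868 cases. A further 2940 of the 16264 pooled peaks without such overlap were also kept, so the replicated list holds some peaks that were absent from a replicate's own list.

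Peaks were assigned to genes with the GENCODE vM21 annotation of GRCm38, whose chromosome ends lay beyond the last peak on all 21 chromosomes. Peaks on unplaced scaffolds were left out, except from the counts and widths of each list, the shares of pooled peaks kept in the replicated list and the correlations between replicates. A promoter was the window of 1 kb either side of any transcript start of a protein-coding transcript, for 21938 protein-coding genes. Breadth was the width of the widest domain touching that window, after peaks were merged over gaps of up to 1 kb, and was 0 without a peak. Neighbouring genes share a domain where it spans both promoters, and 3065 genes share a promoter window with another gene. Distal peaks lay more than 2.5 kb from every annotated transcript start and were counted within 50 kb of a gene's 5′ end. Promoters were classed as high in CpG at an observed over expected ratio of at least 0.6 within 500 bp of the 5′ end, computed from the RefSeq sequence of the same build, which gave 10083 high and 11855 low promoters. The class describes the 5′ end alone, whereas a peak at any coding transcript start counted. A gene of the low class can therefore be marked at another start, whose CpG content was not measured.

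There were 26 gene lists. They were fixed before the data were examined, as were the tests of the comparisons, the alternatives of the processing other than those named below as added, and the rule for naming genes. They cover anterior (paralogs 1 to 5), middle (6 to 8) and posterior (9 to 13) Hox genes, hindbrain and forebrain regulators, pan-neuronal genes, neurotransmission, granule cell lineage, Purkinje cells, monoaminergic and cranial motor neurons, neural progenitors, the Sonic hedgehog pathway, astrocytes, the oligodendrocyte lineage, microglia, endothelial cells, mural and meningeal cells, choroid plexus and ependyma, erythroid cells, liver, heart and skeletal muscle, gut and pancreas, germ cells, pluripotency, housekeeping genes and olfactory receptors. The rule named every Hox gene, the 4 members with the broadest promoter domain and up to 3 members without a promoter peak in every other list, the 10 broadest and 10 most enriched promoters, the 10 most enriched distal peaks, the 10 genes whose rank differed most between replicates, and 5 genes per replicate with the strongest promoter peak absent from the other replicate. Genes named outside this rule were chosen after their values were seen: En2, Gbx2, Atoh1, Pax2, Barhl1, Foxg1, Arx, Otp, Cnp, Mbp and the genes of the last part of the closing section.

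The share of each list with a promoter peak was compared with all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 26 lists and a threshold of 0.05. Exact (Clopper-Pearson) 95% intervals cover counting error only. Median breadth was placed among 10000 random lists of the same size matched on CpG class, and the mean number of distal peaks among 10000 unmatched random lists. A list at or above percentile 97.5 or at or below percentile 2.5 was called apart. These percentiles describe the libraries and are not p-values. In 3 comparisons between lists, the share with a promoter peak was compared by a two-sided Fisher's exact test and mean breadth by a two-sided permutation test of 100000 resamples, with adjustment over the 6 tests. Genes are not independent replicates, so these tests describe how the lists differ within this tissue.

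Replicates were compared by the share of peaks overlapping over at least 50% of the length of either peak, against 100 shuffles of the peaks within chromosomes, and by correlations across pooled peaks with a peak in each replicate. Alternatives were −log10 q of at least 2, enrichment of at least 4, other overlap rules, equal numbers of strongest peaks, the pooled list, each replicate's own list, windows of 0.5 and 2.5 kb, gene 5′ ends only, merging without a gap or over 3 kb, distances of 20 and 100 kb, stratification by CpG class (exact conditional Mantel-Haenszel test), and backgrounds without chemosensory receptors or shared promoters. Unmatched random lists and counting each Hox domain once were added after the data were seen, as were the tests of gene families and explanations in the closing section.

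The code was tested on simulated data for the 21938 genes. Of 200 lists of 16 genes simulated with 8-fold lower odds of a promoter peak, 83% passed an unadjusted p of 0.05. The test was the exact test stratified by CpG class, which 5% of 200 unchanged lists passed. Lists with raised odds were not simulated. Of 200 lists with domains simulated 2-fold wider, 76% reached percentile 97.5, against 3.5% of 200 unchanged lists. Every simulated gene had a domain, and widths did not depend on CpG class, unlike the data, so these rates may not carry over. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, bedtools 2.31.1 and samtools 1.23.1.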

Results

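H3K4me2 was profiled in hindbrain of newborn mice, in 1 group of 2 biological replicates made from pooled animals of both sexes. Replicate 1 had 49498 peaks covering 51.1 Mb and replicate 2 had 45401 peaks covering 54.7 Mb, with median widths of 556 and 707 bp. The authors' list of both replicates pooled held 50132 peaks, and their replicated list kept 36808 of these over 56.5 Mb. Unless stated otherwise, values below are from the replicated list. Where the breadth of a named gene varied by over 1.5 times between this list and the replicates' own lists, or was 0 in one of them, the values of replicates 1 and 2 follow in that order. The design implies 3 questions: where the mark lay, how the replicates compared, and how genes of the hindbrain and its cells compared with genes of other brain regions and other tissues.

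Protein-coding promoters held a large share of the mark. Of 36791 replicated peaks on the 21 chromosomes, 44.0% touched a promoter, against 4.36% ± 0.111 (SD over 100 shuffles) of shuffled peaks. The share was 37.5% in replicate 1 and 38.7% in replicate 2. Promoter peaks were wide and strong, with a median width of 2170 bp and enrichment of 27.6, while the 15218 distal peaks had medians of 629 bp and 4.93. By its highest point, a peak lay at a coding promoter in 40.3% of cases (2.64% when shuffled) and at the start of another transcript in 7.51% (3.73%). It lay in an exon of a coding gene in 3.55% (2.77%), in an intron of a coding gene in 23.2% (34.7%) and elsewhere, outside coding genes, in 25.4% (56.1%). The bodies of non-coding genes were not set apart in these classes. Promoters were kept in the replicated list more often than distal sites, since 94.3% of pooled promoter peaks but 62.2% of pooled distal peaks were retained. The kept share was 8.02% in the lowest decile of enrichment and 100% in each of the upper 5 deciles.

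A promoter peak was found at 14680 of 21938 protein-coding genes (66.9%). Replicate 1 marked 14692 genes and replicate 2 marked 14772. Genes with a CpG-rich promoter at their 5′ end, a class typical of broadly used and developmental genes, were marked at 98.1%, and the remaining genes at 40.4%. The median marked gene had a domain of 2674 bp, and 165 genes had domains over 10 kb.

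The 10 broadest promoter domains by gene included Hox and Zic genes, regulators of development, along with Qk and a predicted gene. A domain of 49.2 kb on chromosome 11 (96297368 to 96346594) covered Hoxb3, Hoxb4, Hoxb5 and Hoxb6, and measured 45.1 ± 6.34 kb (SD, n = 2) in the replicates. Zic1 and Zic4, zinc finger genes of the cerebellar granule lineage, shared a domain of 41.7 kb on chromosome 9 (91348474 to 91390174), with 41.2 ± 0.677 kb in the replicates. Qk, an RNA-binding protein of glia, had 33.0 kb on chromosome 17 (10289430 to 10322383), but 23.5 kb in replicate 1 against 33.0 kb in replicate 2. Zic2, Zic5 and the predicted gene Gm10837 shared 32.4 kb on chromosome 14 (122459677 to 122492055). The most enriched promoters were other genes. Epb41, which encodes a protein of the membrane skeleton, and its neighbour Gm10300 had an enrichment of 62.5, and the immediate early gene Egr1 had 61.0. Col27a1 had 59.2 and Ank3, which encodes the ankyrin of the axon initial segment, had 58.8. E2f8, Gcnt4, Kif26b, Rreb1 and Cd109 lay between 56.6 and 57.4. All 10 of these promoters had domains under 7 kb, from 1.90 kb at Gm10300 to 6.67 kb at Ank3.

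Hox genes, which set position along the body axis in the order of their paralog numbers, were on average marked more broadly in paralogs 1 to 5 than in paralogs 9 to 13, with narrow domains at some anterior genes, such as Hoxb1 and Hoxd1. All 15 genes of paralogs 1 to 5 had a promoter peak, against 7 of 16 genes of paralogs 9 to 13, the group used in the posterior trunk and limbs. Mean breadth was 19.9 ± 18.1 kb (SD over genes) for the anterior group and 0.312 ± 0.408 kb for the posterior group, whose mean was 0.1995 and 0.340 kb in the replicates. In the HoxA cluster, Hoxa1, Hoxa2 and Hoxa3 shared a domain of 29.5 kb on chromosome 6 (52156139 to 52185673), which measured 28.3 ± 1.29 kb (SD, n = 2) in the replicates, and Hoxa4 and Hoxa5 had 6.64 and 4.52 kb, the latter with 9.14 and 4.47 kb in the replicates. In the HoxD cluster, Hoxd3 and Hoxd4 shared 14.4 kb on chromosome 2 (74726740 to 74741176), with 15.1 ± 1.04 kb in the replicates.

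Beside the HoxB domain of 49.2 kb, Hoxb2 had 7.54 kb and Hoxb1 1.33 kb. In HoxC, Hoxc4 had 8.73 kb and Hoxc5 2.52 kb, and Hoxd1 had 1.83 kb. Of the middle paralogs, Hoxa6 had 1.47 kb (9.14 and 1.45 kb in the replicates), Hoxa7 0.943 kb, Hoxc6 0.359 kb (0.280 and 0 kb) and Hoxd8 1.46 kb. A stronger peak lay within 1 kb of the 5′ end of Hoxc6, with an enrichment of 15.99 in the replicated list. In replicates 1 and 2 it had 12.09 and 15.98. It was not counted, since the promoter definition used only starts of coding transcripts. Hoxb7 and Hoxb8 shared 4.87 kb, but in replicate 2 Hoxb7 had 1.53 kb and Hoxb8 had no promoter peak, against a shared 4.74 kb in replicate 1. Replicate 2 did have a peak inside the Hoxb8 gene (96284038 to 96285133, enrichment 10.8), which lay outside the promoter window. Hoxc8 had a peak only in replicate 2 (0.388 kb). The posterior genes with a peak were Hoxa13 (0.959 kb), Hoxb9 (1025 bp; 0.598 and 0.943 kb in the replicates), Hoxb13 (0.399 kb; 0.190 and 0.217 kb), Hoxd9 (1026 bp) and Hoxd13 (0.627 kb), along with Hoxc10 (0.357 kb; 0 and 0.205 kb) and Hoxc13 (0.593 kb; 0 and 0.613 kb), which had none in replicate 1. No replicated promoter peak was found at Hoxa9, Hoxa10, Hoxa11, Hoxc9, Hoxc11, Hoxc12, Hoxd10, Hoxd11 or Hoxd12, of which Hoxd11 had one in replicate 2 (1.01 kb).

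The difference of 19.6 kb in mean breadth between anterior and posterior Hox genes had an adjusted p of 4e-05 in a two-sided permutation test, from an unadjusted p of 2e-05, the smallest that the permutations can give, and the shares of marked genes differed with an adjusted p of 9.79e-04 in a two-sided Fisher's exact test. Because neighbouring Hox genes share domains, the test was repeated with each domain counted once, which gave 12.6 kb over 10 anterior domains against 0.312 kb for the 16 posterior genes (permutation p = 2e-05, the smallest possible). Among random lists of the same size and CpG class, median breadth lay at percentile 100 for paralogs 1 to 5 (14.4 kb) and at percentile 0 for paralogs 9 to 13 (0 kb). Paralogs 6 to 8 lay at percentile 0.945 with a median of 1.46 kb (3.03 and 1.16 kb in the replicates), but this call was lost in many alternatives. Their percentile was 87.3 in replicate 1's own list, in which Hoxa6 joined a domain of 9.14 kb, 82.8 in the pooled list, 79.5 with a window of 2.5 kb, 96.5 with merging over 3 kb and 34.6 with random lists not matched on CpG class. Against all other genes, the share marked was higher for paralogs 1 to 5 (adjusted p = 0.00818, Fisher's exact test), and this call was lost when only gene 5′ ends were counted (adjusted p = 0.149). The lower share for paralogs 9 to 13 did not pass (43.8%, exact 95% interval 19.8 to 70.1%, adjusted p = 0.0949, Fisher's exact test). It passed when stratified by CpG class (adjusted p = 2.57e-04), at an enrichment of at least 4 (0.00346), in replicate 1's own list (0.00993) and without chemosensory receptors in the background (0.0373, exact tests). For paralogs 6 to 8, 7 of 8 were marked (adjusted p = 0.352, Fisher's exact test).

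**Figure D1:**
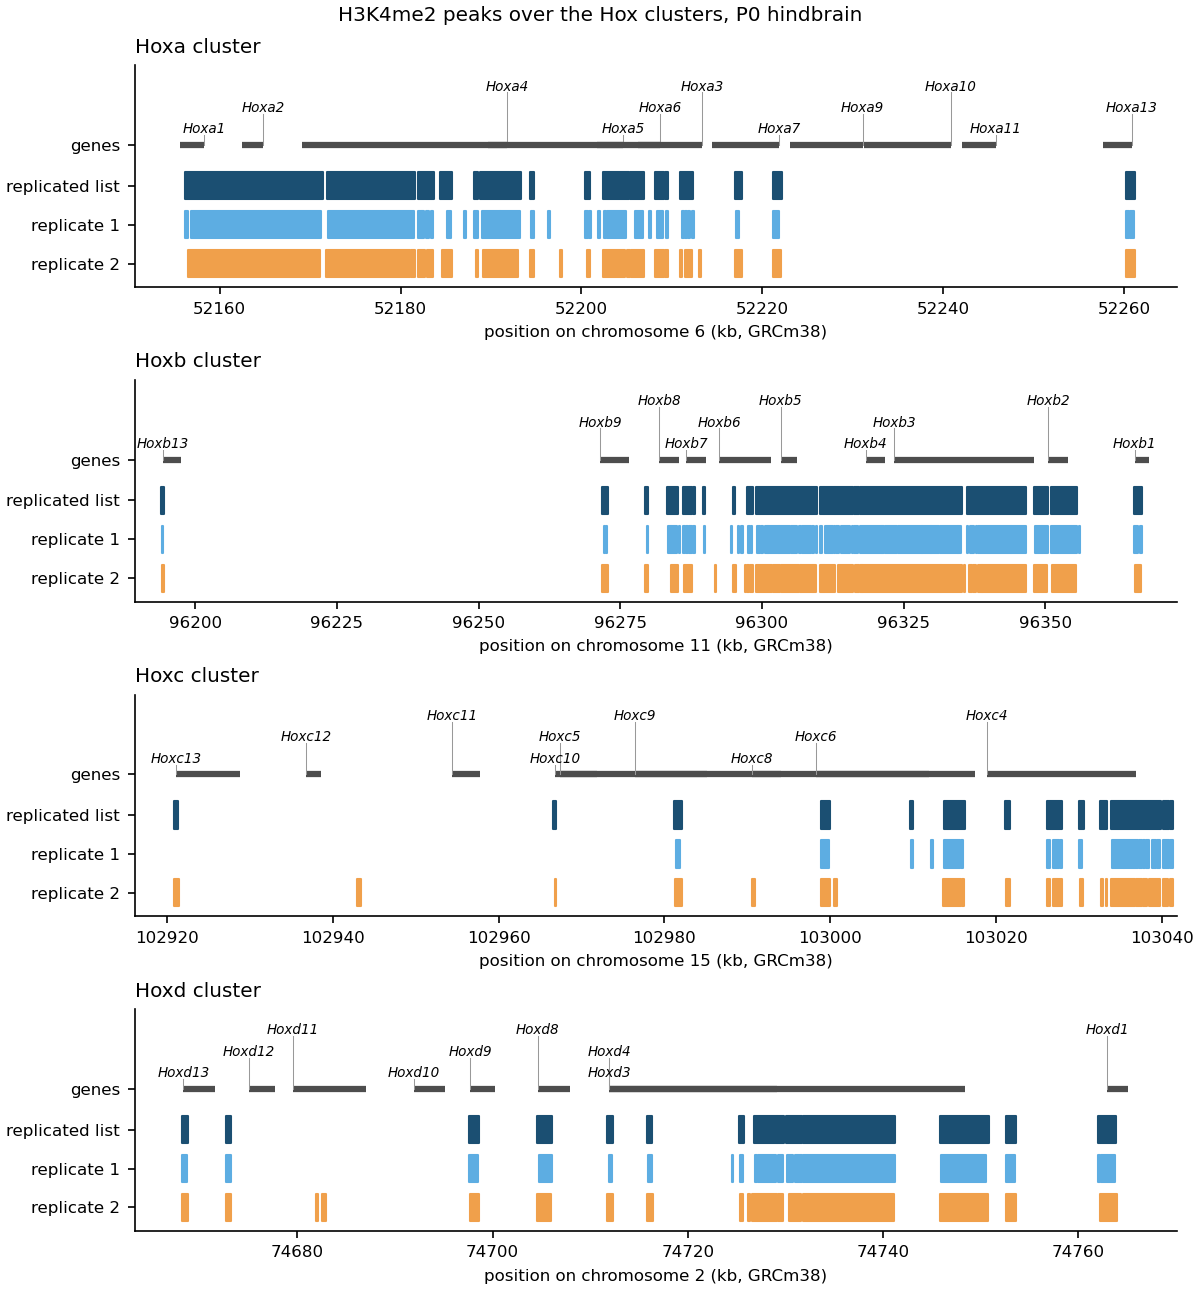
Replicated peaks and the peaks of replicate 1 and replicate 2 along the 4 Hox clusters, with position in kb on the horizontal axis and genes drawn above the peaks. Peaks are dense from Hoxa1 to Hoxa3, over Hoxb3 to Hoxb6 and at Hoxd3 and Hoxd4, and sparse over paralogs 9 to 13 in all 3 lists.

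Regulators of hindbrain and forebrain identity were nearly all marked, but over very different widths. Of 26 hindbrain regulators 25 had a promoter peak, and all 27 forebrain regulators had one. Mean breadth was 7.21 ± 5.45 kb (SD over genes) for the hindbrain list and 2.20 ± 1.87 kb for the forebrain list. Lhx1, a LIM homeobox gene of Purkinje cells and hindbrain interneurons, had 20.7 kb on chromosome 11 (84511922 to 84532606), with 18.7 ± 2.65 kb (SD, n = 2) in the replicates. Its relative Lhx5 had 17.5 kb, En1, a gene of the midbrain and hindbrain boundary, had 14.1 kb, and Lmx1b, required for serotonergic neurons, had 11.8 kb.

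Other wide hindbrain domains lay at Barhl1 (11.3 kb), Pax2 (10.9 kb), Gbx2 (9.24 kb), Atoh1 (7.92 kb; 5.20 and 7.85 kb in the replicates) and En2 (7.29 kb; 11.4 and 11.3 kb). The forebrain list was led by Lhx2 with 7.49 kb, where replicate 1 had 10.2 kb and replicate 2 had 2.98 kb. Gsx1 followed with 6.59 kb, Eomes with 5.31 kb and Satb2, a gene of cortical projection neurons, with 4.75 kb. Foxg1, the regulator of the telencephalon, had a domain of 0.277 kb (0.205 and 0.577 kb in the replicates) with enrichment 4.23, and Arx had 0.336 kb. Otp, a gene of the hypothalamus, had 1.64 kb in the replicated list and no promoter peak in either replicate's own list. Phox2b, which specifies visceral motor neurons, was the hindbrain regulator without a replicated peak, and had 0.248 kb in replicate 2.

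The difference of 5.02 kb in mean breadth had an adjusted p of 6e-05 in a two-sided permutation test, and was 4.65 kb in replicate 1's own list and 5.36 kb in that of replicate 2. The shares of marked genes did not differ detectably (96.2 against 100%, p = 0.491, two-sided Fisher's exact test). Against random lists matched on CpG class, the hindbrain median of 6.89 kb lay at percentile 100 and the forebrain median of 1.61 kb at percentile 0.03. The forebrain call was lost when peaks were merged over 3 kb (percentile 17.3) or when random lists were not matched on CpG class (percentile 24.5), whereas the hindbrain call held in each alternative. The share of marked genes was above that of other genes for both lists, with adjusted p of 0.00166 for hindbrain and 1.81e-04 for forebrain regulators (two-sided Fisher's exact test). Stratified by CpG class in an exact test, the hindbrain call was lost (adjusted p = 0.163) and the forebrain call was kept (adjusted p = 0.00532). The forebrain call was lost at an enrichment of at least 4 (adjusted p = 0.0663, Fisher's exact test) and with gene 5′ ends only (adjusted p = 0.107).

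**Figure D2:**
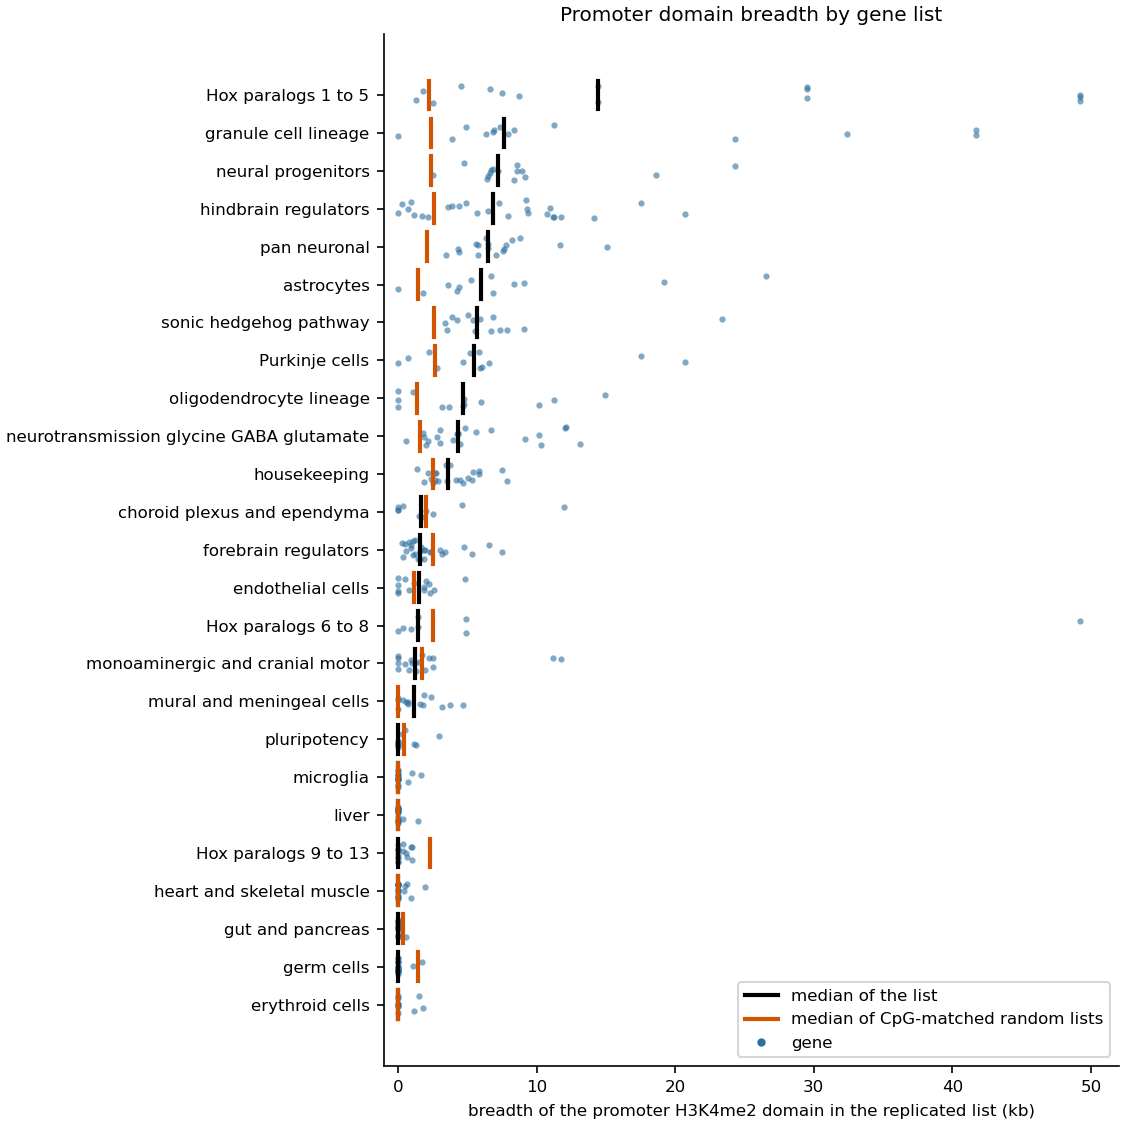
Promoter domain breadth in kb of each gene (points) in the fixed lists other than olfactory receptors, with the median of each list in black and that of random lists matched on CpG class in orange. Anterior Hox genes, the granule cell lineage, neural progenitors and hindbrain regulators have medians from 6.89 to 14.4 kb, while posterior Hox genes and genes of other tissues have medians of 0.

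Genes of brain cells carried wide domains and genes of other tissues mostly carried none. Of 56 genes of neurons, progenitors, astrocytes and oligodendrocytes, 52 had a promoter peak, against 10 of 66 genes of liver, muscle, gut and pancreas, and germ cells. Mean breadth was 7.30 ± 5.31 kb (SD over genes) against 0.148 ± 0.408 kb. The widest domains of these brain lists lay at Nfib (26.6 kb), Pax6 (24.3 kb), Nfia (19.2 kb), Sox2 (18.6 kb; 12.1 and 18.7 kb in the replicates) and Elavl4 (15.1 kb). The difference of 7.16 kb had an adjusted p of 4e-05 in a two-sided permutation test, from an unadjusted p of 2e-05, the smallest that the permutations can give. The shares of 92.9 and 15.2% differed with an adjusted p of 1.28e-18 in a two-sided Fisher's exact test. Neither test was matched on CpG class, in which the lists differed. CpG-rich promoters belonged to 9 of 17 pan-neuronal, 10 of 15 progenitor, 4 of 12 astrocyte and 4 of 13 oligodendrocyte genes. They belonged to 0 of 16 liver, 1 of 18 muscle, 2 of 14 gut and pancreas and 6 of 18 germ cell genes.

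Pan-neuronal and neurotransmission genes were marked without exception. All 17 pan-neuronal genes had a promoter peak (adjusted p = 0.00329, Fisher's exact test) with a median breadth of 6.52 kb (6.09 and 6.81 kb in the replicates), at percentile 100. Elavl4, an RNA-binding protein of neurons, had 15.1 kb, Celf4 11.7 kb, Stmn2 8.78 kb and the neuronal tubulin gene Tubb3 8.23 kb. All 22 genes of glycine, GABA and glutamate neurotransmission were marked (adjusted p = 0.00100, Fisher's exact test), and 8 of them were CpG-rich at their 5′ end. Their median was 4.34 kb, at percentile 100. The widest lay at the vesicular glutamate transporter Slc17a6 (13.1 kb), the GABA synthesis gene Gad1 (12.2 kb), the vesicular transporter of inhibitory neurons Slc32a1 (12027 bp) and the NMDA receptor subunit Grin2b (10.3 kb).

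Genes of the developing cerebellum had some of the widest domains. In the granule cell lineage 13 of 14 genes were marked (adjusted p = 0.0732, Fisher's exact test; 0.0495 with gene 5′ ends only), and the median of 7.64 kb lay at percentile 100. Zic1, Zic4, Zic2 and Pax6 led with 41.7, 41.7, 32.4 and 24.3 kb, and Gabra6, the receptor subunit of mature granule cells, had no peak in either replicate. Among Purkinje cell genes 11 of 12 were marked (adjusted p = 0.164, Fisher's exact test), with a median of 5.52 kb at percentile 100. After Lhx1 and Lhx5 came Foxp2 (6.54 kb) and Grid2 (6.06 kb), while Pcp2, a marker of differentiated Purkinje cells, had no peak. Monoaminergic and cranial motor neuron genes were marked in 14 of 18 cases (adjusted p = 0.537, Fisher's exact test), with a median of 1.25 kb at percentile 24.5. Lmx1b had 11.8 kb and Gata3 11.2 kb (8.26 and 15.5 kb in the replicates), Chat and Slc18a3 shared 2.56 kb, and the enzymes Dbh and Ddc had no peak.

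Progenitor and glial genes were marked in an uneven way. All 15 neural progenitor genes had a peak (adjusted p = 0.00818, Fisher's exact test), with a median of 7.19 kb at percentile 100. Besides Pax6 and Sox2, Msi1 had 9.19 kb and the Notch target Hes5 8.94 kb. All 14 genes of the Sonic hedgehog pathway, which drives granule progenitor division, were marked, with a median of 5.73 kb at percentile 100. The receptor Ptch1 had 23.4 kb (23.0 ± 0.350 kb in the replicates; SD, n = 2), the co-receptor Boc 9.08 kb, Ccnd1 7.84 kb and Gli2 7.36 kb. The share for this pathway passed the test (adjusted p = 0.0137, Fisher's exact test) but not when stratified by CpG class (adjusted p = 0.163). Among astrocyte genes 11 of 12 were marked, with a median of 5.99 kb at percentile 100. Nfib, Nfia, the glutamate transporter Slc1a3 (9.10 kb) and Sox9 (8.37 kb) led, and Gfap, an intermediate filament gene of mature astrocytes, had a peak only in replicate 1 (0.314 kb). The astrocyte share did not pass (adjusted p = 0.164, Fisher's exact test) and passed when stratified by CpG class (adjusted p = 0.0241), in the pooled list (0.0228), in replicate 1's own list (0.0190) and with a window of 2.5 kb (0.0236, exact tests).

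In the oligodendrocyte lineage the widest domains lay at genes of the early lineage, Nkx2-2 (14.9 kb), Olig2 (11.3 kb), Pdgfra (10.2 kb) and Gpr17 (5.96 kb; 3.98 and 6.33 kb in the replicates). Myelin genes were divided, with no peak at Mag, Mog and Plp1 but 4.67 kb at Cnp and 3.15 kb at Mbp, the last 2 named after their values were seen. The list had 10 of 13 genes marked (adjusted p = 0.618, Fisher's exact test) and a median of 4.67 kb at percentile 100 after rounding, with medians of 3.03 and 4.70 kb in the replicates at percentiles 99.6 and 100 after rounding.

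Markers of other cells that a hindbrain dissection holds differed from list to list, with most vascular and choroid plexus genes marked and most microglial and erythroid genes not. Of 15 microglial genes 3 were marked, Hexb (1.69 kb), Tmem119 (1.01 kb; 0 and 0.992 kb in the replicates) and P2ry12 (0.699 kb; 0.684 and 0.298 kb), and none was found at Aif1, C1qa or C1qb. The lower share passed the test (20.0%, exact 95% interval 4.33 to 48.1%, adjusted p = 0.00100, Fisher's exact test) but not when stratified by CpG class (adjusted p = 0.106). Of 14 endothelial genes 10 were marked (adjusted p = 1, Fisher's exact test), among them Esam (4.80 kb), Cdh5 (2.57 kb; 1.71 and 2.75 kb in the replicates), Sox17 (2.3 kb) and the growth factor receptor Kdr (2.23 kb, enrichment 50.5), and Ly6c1 and Slco1a4 had no peak. Of 14 mural and meningeal genes 11 were marked (adjusted p = 0.618, Fisher's exact test; 0.0241 stratified by CpG class), with 4.70 kb at Pdgfrb (2.66 and 4.56 kb in the replicates), 3.76 kb at Foxc1 (2.93 and 10.4 kb), 3.19 kb at Vtn and 2.4 kb at Kcnj8, and no peak at Col3a1. Replicate 2 marked 11 endothelial and 13 mural genes and replicate 1 marked 9 and 10, and Pecam1 (1.11 kb), Foxs1 (2.22 kb) and Lum (0.385 kb) had a peak only in replicate 2. Choroid plexus and ependymal genes were marked in 7 of 10 cases (adjusted p = 1, Fisher's exact test), led by Otx2 (11978 bp), the cilia regulator Foxj1 (4.66 kb), Kl (2.51 kb) and Msx1 (2.00 kb; 3.55 and 4.12 kb in the replicates), without peaks at Folr1 and Kcne2, and with one at Ttr in replicate 1 only (0.190 kb). Erythroid genes were marked in 3 of 10 cases, Epor (1.82 kb; 3.25 and 1.86 kb in the replicates), Klf1 (1.5 kb) and Gypa (1.19 kb), and not at Alas2, Gata1 or the globin gene Hba-a1. Their lower share (30.0 against 66.9% of other genes) passed the test (adjusted p = 0.0326, Fisher's exact test). This call was lost when stratified by CpG class (−10.4 percentage points, adjusted p = 0.848, exact test). It was also lost at an enrichment of at least 4 (−36.1 points, adjusted p = 0.0651, Fisher's exact test). The same test lost it with gene 5′ ends only (−34.0 points, 0.0780) and without genes sharing a promoter window (−32.9 points, 0.0704). Median breadth of these 5 lists lay between percentiles 28.3 and 86.5, so none was called apart from random lists. A low call was not possible for microglial, mural and erythroid genes, whose random lists had a median of 0.

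Lists of unsampled tissues gave the background of the measure. Liver genes were marked in 2 of 16 cases, Apoa1 (1.47 kb; 0 and 1.42 kb in the replicates) and Apob (0.388 kb), and Alb, Afp and Ahsg had no peak. Muscle genes were marked in 5 of 18 cases, the widest being Myod1 (1.93 kb), Tnni3 (0.971 kb), Gata4 (0.636 kb) and Myl2 (0.504 kb; 0.288 and 0.526 kb in the replicates), with none at Acta1, Ckm or Myf5. Among gut and pancreas genes Cdx1 alone of 14 was marked (0.608 kb; 0.382 and 0.530 kb in the replicates), and Apoa4, Cdx2 and Cpa1 were not. Germ cell genes were marked in 2 of 18 cases, Zpbp (1.70 kb) and Dazl (1.08 kb), and not at Acr, Ddx4 or Dmrtb1. The share was below that of other genes in all 4 lists, with adjusted p of 6.97e-05, 0.00203, 4.75e-05 and 1.93e-05 (Fisher's exact test). Stratified by CpG class in an exact test, the muscle call was lost (adjusted p = 0.270; also 0.0670 with a window of 2.5 kb), while liver (adjusted p = 0.0445), gut and pancreas (adjusted p = 5.23e-04) and germ cells (adjusted p = 5.44e-08) kept theirs. Pluripotency genes were marked in 5 of 11 cases (adjusted p = 0.255, Fisher's exact test), with 2.97 kb at Esrrb, 1.30 kb at Tfcp2l1, 1.17 kb at Utf1 and 0.528 kb at Dppa3, and none at Dppa2, Dppa4 or Dppa5a. Median breadth was 0 in these 5 lists, at percentiles from 4.71 to 35.4 of random lists matched on CpG class. A median of 0 is the lowest possible, so no lower percentile could be reached and no low call was possible with this matching.

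Olfactory receptors, used by sensory neurons of the nose, were marked at 4 of 1135 genes (0.352%, exact 95% interval 0.0961 to 0.900%): Olfr94 (1.53 kb), Olfr658 (0.480 kb), Olfr452 (0.386 kb; 0.199 and 0 kb in the replicates) and Olfr1033 (0.383 kb). Stratified by CpG class, the adjusted p was 2.08e-261. Housekeeping genes served as the opposite reference. All 22 were marked (adjusted p = 0.00100, Fisher's exact test), with 7.88 kb at Tubb5, 7.49 kb at Ywhaz, 5.88 kb at Polr2a and 5.85 kb at Chmp2a, the last of which had 1.72 and 1.51 kb in the replicates. Their median of 3.64 kb lay at percentile 99.7, a call that was lost with gene 5′ ends only (percentile 97.1) and without merging (percentile 95.5). In all, 8 of the 26 lists had a higher share of marked genes than other genes and 7 had a lower one. Breadth lay at or above percentile 97.5 in 11 lists and at or below percentile 2.5 in 3, a side that not every list could reach. The lists are not separate sets of genes, so these counts are not independent. Among others, 10 of 26 hindbrain regulators, 6 of 14 granule cell, 3 of 12 Purkinje and 3 of 14 Sonic hedgehog genes were also in another list.

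**Figure D3:**
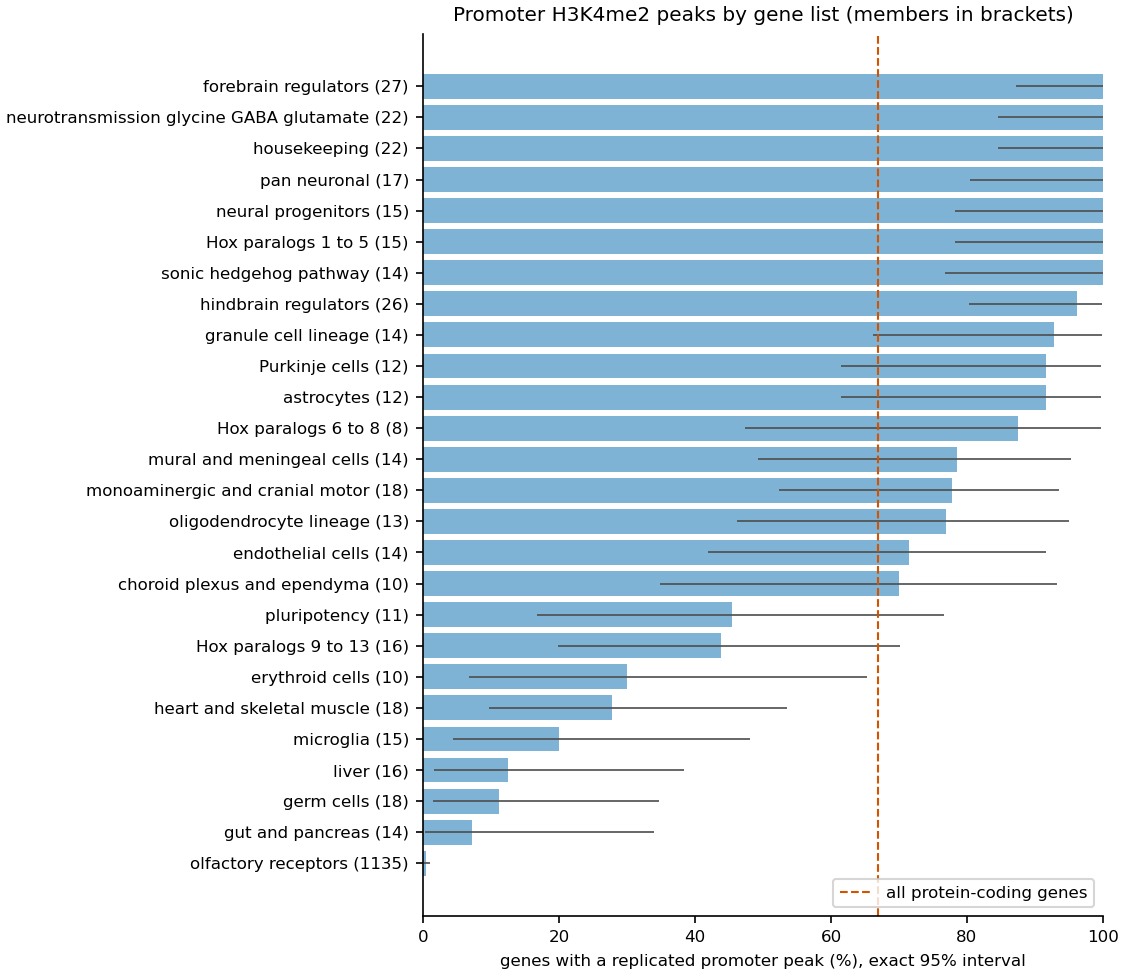
Percent of each list's genes with a promoter peak in the replicated list (bars with exact 95% intervals), with the share over all protein-coding genes as a dashed line. Lists of neurons, progenitors, astrocytes and oligodendrocytes reach 76.9 to 100% and lists of other tissues lie between 0.352 and 45.5%.

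Of the 26 lists, 10 had more distal peaks nearby than most unmatched random lists, hindbrain and forebrain regulators among them. Hindbrain regulators had a mean of 3.38 distal peaks within 50 kb, against 0.692 for the median of random lists, and lay at percentile 100. Forebrain regulators had 1.78, also above random lists (percentile 100 after rounding). The remaining lists above percentile 97.5 were middle Hox genes (2.75), the granule cell lineage (2.64), astrocytes (2.5), neural progenitors (2.27), the oligodendrocyte lineage (2.08), anterior Hox genes (1.73), the Sonic hedgehog pathway (1.71) and pan-neuronal genes (1.65). Distal means were higher in each replicate's own list for all 26 lists, with 5.5 and 4.35 for hindbrain regulators in replicates 1 and 2, 7.25 and 5.38 for middle Hox genes, 5.33 and 3.93 for anterior Hox genes, 4.14 and 3.43 for granule cells, 4 and 2.93 for progenitors, 3.23 and 3.15 for oligodendrocytes, 3.07 and 2.71 for the Sonic hedgehog pathway and 3.35 and 2.24 for pan-neuronal genes. These 8 lists, forebrain regulators and astrocytes passed in each replicate's own list. The calls for anterior Hox and pan-neuronal genes were lost at an enrichment of at least 4 (percentiles 84.9 and 91.6), and that for middle Hox genes within 20 kb (percentile 92.0). Neighbouring Hox genes lie within 50 kb of one another and can count the same distal peaks. Their distal counts were not repeated with each peak used once. Neurotransmission genes, whose promoters were all marked, had 0.591 distal peaks at percentile 36.7 (0.864 and 1 in the replicates). Posterior Hox genes (1.31), Purkinje cells (1.33; 2.33 and 1.75 in the replicates), choroid plexus (1.5), endothelial (1.14; 1.36 and 1.79), mural (1.07; 1.36 and 1.79), microglial (1.07) and housekeeping (1.14) genes lay between percentiles 88.3 and 97.1. Within 20 kb, Purkinje (percentile 99.3), mural (99.6) and choroid plexus (97.6) genes passed. Purkinje genes also passed in the pooled list and in replicate 1's own list (98.7 in each), and posterior Hox genes in the pooled list (97.6) and within 100 kb (99.97). Monoaminergic and motor (0.722; 1.11 and 0.833 in the replicates), erythroid (0.4; 0.8 and 0.6), liver (0.813), muscle (1.11), gut and pancreas (0.786), germ cell (0.778; 1.17 and 1.28) and pluripotency (0.909) genes lay between percentiles 21.8 and 92.2. Olfactory receptors had 0.0661 at percentile 0.

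The most enriched distal peaks lay outside coding genes in 7 of 10 cases. The strongest lay on chromosome 4 (106838688 to 106841251), 34548 bp from Acot11, with an enrichment of 53.0. The next was in an intron of Tns3, a focal adhesion gene, on chromosome 11 (8622359 to 8625491), with 52.4. Peaks outside coding genes followed on chromosome 17 (88255479 to 88257629), 184414 bp from Foxn2, and on chromosome 3 (9345983 to 9347987), 96388 bp from Zbtb10, with 50.9 and 48.2. Peaks in an intron of Pura on chromosome 18 (36285259 to 36288475) and in an exon of Prr7 on chromosome 13 (55470682 to 55473931) had 48.5 and 48.0. The peaks nearest to the histone gene H3f3a, Hook2, Copz2 and Meis1, which encodes a partner of Hox proteins, had 46.9, 45.2, 45.0 and 44.6, and the last lay on chromosome 11 (19025713 to 19027957), 7881 bp from Meis1.

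The replicates marked nearly the same genes. A promoter peak was present in both at 14599 genes, in replicate 1 only at 93 and in replicate 2 only at 173. Of replicate 1's peaks 78.6% overlapped a peak of replicate 2 (2.98% ± 0.0758 over shuffles), and 77.1% of replicate 2's peaks overlapped one of replicate 1 (3.11% ± 0.0726). Peaks without any overlap were weak, with median enrichments of 3.40 and 3.26, and none of them reached 10. Across 33868 pooled peaks with a peak in each replicate, log2 enrichment correlated with Pearson's r = 0.955 and Spearman's rho = 0.938. These correlations are across peaks, which are not independent replicates. Within classes they were lower, with r = 0.931 at promoters and 0.896 at distal sites. Across the 14599 genes, rho of promoter enrichment was 0.820 and r of log2 breadth was 0.944, again across genes rather than independent replicates.

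Single genes differed more. The largest rank differences were at Icam4, a cell adhesion gene, which lay at percentile 7.08 of promoter enrichment in replicate 1 and 92.8 in replicate 2, and at Tmem102, which lay at 83.2 and 1.27. Evc2, Npr2, Rasgef1c, Kcnh2 and Cby3 also ranked higher in replicate 2, and 1700092M07Rik, Bicd1 and Ak9 higher in replicate 1. In 5 of these 10 genes the lower replicate had a stronger peak within 1 kb outside the promoter window. They were Icam4, Tmem102, Evc2, 1700092M07Rik and Cby3, and this check was chosen after the values were seen. With that 1 kb included, the enrichment of Icam4 in replicate 1 rose from 10.02 to 32.46, against 41.65 in replicate 2. That of Tmem102 in replicate 2 rose from 4.48 to 30.99, against 28.66 in replicate 1. The low ranks of Icam4 and Tmem102 therefore hold for the promoter window alone. The strongest promoter peaks of replicate 1 at genes without a promoter peak in replicate 2 were at Fam167b (6.91), Tnfrsf25 (6.83), Ccdc183 (5.53), Nrn1l (5.28) and Trp63 (5.18). Those of replicate 2 at genes without one in replicate 1 were at Pdia2 (38.2), Tsks (37.9), Cldnd2 (34.4), Astl (32.8) and Ssc5d (31.2), where replicate 1 had a peak within 1 kb outside the promoter window. With 2 replicates, no difference between them was tested for single genes.

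**Figure D4:**
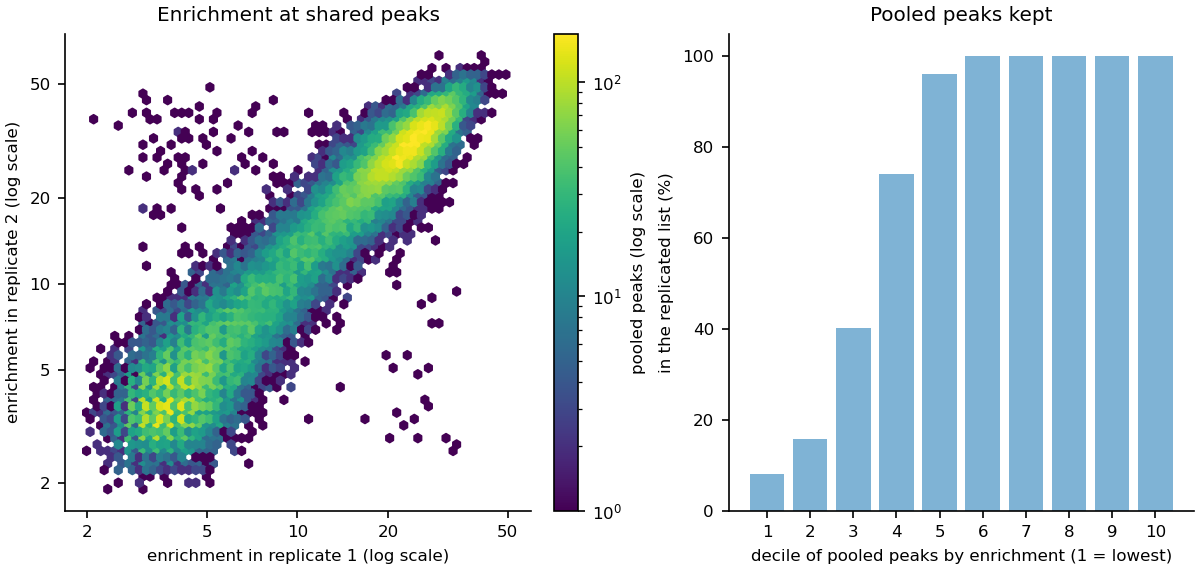
Left, enrichment of pooled peaks in replicate 1 (horizontal) and replicate 2 (vertical), both on log axes, over 33868 peaks with a peak in each replicate; right, percent of pooled peaks kept in the replicated list by decile of enrichment. Enrichment is correlated between the replicates (r = 0.955) but is higher in replicate 2 at 75.8% of these peaks, and the kept share goes from 8.02% to 100%.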

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

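A pair of results lay in data outside the comparisons of promoters and gene lists in the report, and no explanation of either was tested. First, 17 replicated peaks lay on 6 scaffolds outside the 21 chromosomes. Their median enrichment was 5.70. The one with the highest −log10 p had an enrichment of 4.03, whereas the 14284 chromosomal peaks with a −log10 p at least as high began at an enrichment of 12.1. Second, 2762 replicated peaks had their highest point at the start of a transcript other than the coding transcripts of protein-coding genes. They made up 7.51% of the peaks on chromosomes, against 3.73% of shuffled peaks, and values for the non-coding genes are given below.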

How the results depend on the processing

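All alternatives were chosen before the data were examined except random lists not matched on CpG class and counting each Hox domain once, which were chosen after seeing the data. No paired analysis was possible because the series has 1 group. The cause of the changes below was not tested.

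The breadth differences kept their direction and their side of the threshold under each alternative run: 3.27 to 6.84 kb between hindbrain and forebrain regulators (adjusted permutation p from 3e-05 to 2.1e-04), 7.10 to 30.5 kb between anterior and posterior Hox genes, and 5.13 to 8.45 kb between brain cells and other tissues. So did the shares of marked genes for Hox genes (difference 42.9 to 75 percentage points) and for brain cells against other tissues (67.4 to 82.3 points). None of the alternatives for these comparisons matched the lists on CpG class. The number of lists above other genes was 7 to 9 and below them 5 to 8. Lists at or above percentile 97.5 were 10 to 11 for breadth and 8 to 12 for distal peaks. Lists at or below percentile 2.5 for breadth were 3, but 1 with merging over 3 kb and 5 with unmatched random lists. They were fewer than 3 in the pooled list, in replicate 1's own list and with a window of 2.5 kb, where Hox paralogs 6 to 8 left this side.

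The share of replicate 1's peaks found in replicate 2 was 82.4% with 1 bp of overlap, 61.5% with 50% of both peaks, 82.7% at a −log10 q of at least 2, 88.6% at an enrichment of at least 4, 82.5% with as many strongest peaks as in the smaller list and 97.6% for the 20000 strongest. For replicate 2's peaks these shares were 80.3, 67.1, 78.3, 88.4, 75.0 and 94.8%. The correlation was 0.952 with 1 bp, 0.960 with 50% of both, 0.948 at an enrichment of at least 4 and 0.959 for −log10 p. Of pooled peaks, 78.4% were kept at a −log10 q of at least 2 and 99.3% at an enrichment of at least 4.

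The share of peaks at promoters was 52.4% at an enrichment of at least 4, 34.2% in the pooled list, 42.7% with a window of 500 bp, 48.8% with 2.5 kb, 37.9% with gene 5′ ends only, and 37.5 to 38.7% without either replicate. Genes with a promoter peak were, in the same order, 66.1, 67.7, 66.3, 68.1 and 64.0%, and 66.97 to 67.3% without either replicate.

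Results that reversed were not past the threshold in the test of shares. The share of marked hindbrain less forebrain regulators, −3.85 percentage points, became 3.28 at an enrichment of at least 4, 3.56 with a window of 500 bp and 10.8 with gene 5′ ends only, and was −0.142 to 3.70 without either replicate. The share less that of other genes became −1.51 points with gene 5′ ends only for Hox paralogs 6 to 8. For endothelial genes it became −8.98 at an enrichment of at least 4 and −0.255 without chemosensory receptors, and was −2.69 to 11.2 without either replicate. For choroid plexus it became −6.12 at an enrichment of at least 4, −4.01 with gene 5′ ends only and −1.68 without chemosensory receptors. The breadth percentile of Hox paralogs 6 to 8 became 82.8 in the pooled list, 79.5 with a window of 2.5 kb and 96.5 with merging over 3 kb, and was 0.41 to 87.3 without either replicate.

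Under the alternatives, single lists lost a call in 20 cases and gained one in 21, which concerned promoter peaks in 22, breadth in 9 and distal peaks in 10, and 11 results of single lists reversed, as given above. The reversals in breadth of Hox paralogs 6 to 8 also lost a call, and are not among those 20 cases. The smallest peak counts were 33315 and 30883 in replicates 1 and 2. What sequencing depth limits could not be measured, since peak lists hold no counts.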

Other observations

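Families of genes sharing a symbol stem showed where broad and absent marks lay. Members of the fixed lists, such as Sox2, Sox9 and Nkx2-2, were not left out of the families. The families, non-coding genes and chromosomes in this part, and the tests of CpG content, of signal near the calling threshold, of chance and of vascular peaks away from promoters, were chosen after the result was seen. All 19 Sox genes, transcription factors of many lineages, had a promoter peak, with a median breadth of 6.45 kb, and all 20 semaphorins, which guide axons, had one with 4.63 kb. The non-clustered Pcdh genes had 7.74 kb, the Wnt receptors of the Fzd family 5.36 kb and the Klf factors 4.75 kb, whereas Wnt genes had 2.44 kb at percentile 51.8. The clustered Pcdha genes, which give neurons their surface identity, were marked at 1 of 12 genes although 11 had CpG-rich promoters (adjusted p = 2.52e-15, exact test stratified by CpG class over 269 families). Of the other clustered families, Pcdhga had 11 of 12 marked, a higher share that passed in the same exact test (adjusted p = 0.0380) but not without stratification (adjusted p = 0.161), and the lower share of Pcdhb, 4 of 22, did not pass when stratified (adjusted p = 0.116). Mitochondrial ribosomal genes were marked narrowly, with 2.12 kb for the 49 Mrpl genes (percentile 0.08) and 2.11 kb for the 29 Mrps genes (percentile 0.395). Nkx genes, many of them regulators of ventral or non-neural tissue, were marked at 10 of 14 genes, with a median of 1.18 kb (percentile 0.05).

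Some non-coding genes that start away from coding starts also touched broad domains. Among them were C130071C03Rik on chromosome 13 with 33.4 kb (33.1 and 33.4 kb in the replicates), Pantr2 with 24.3 kb, Mir9-3hg, host of a neural microRNA, with 20.6 kb and Mir124-2hg with 18.3 kb. Peaks were found at 14.4% of 5327 lincRNA genes, 206 of 1589 antisense genes, 33.7% of 407 processed transcripts, 7.64% of 1675 miRNA genes, 4.37% of 1260 snoRNA genes and 1.98% of 9534 processed pseudogenes.

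Domains at forebrain regulators were narrow against lists matched on CpG class, a pattern for which weaker peak signal is a candidate explanation. Forebrain regulators had a median enrichment of 13.6, against 29.6 for all marked genes, and among random lists matched on enrichment their median breadth lay at percentile 65.5. This cannot decide the matter, because those random lists were drawn from marked genes and not matched on CpG class. Without CpG matching the pattern was not called in any case (percentile 24.5). Enrichment and breadth also come from the same peaks. Hindbrain regulators argue against signal alone as a rule for regulators, since they had a similar median enrichment of 14.3 and lay at percentile 100 in the same test. CpG content was not decided, because the pattern was itself called from random lists matched on CpG class (percentile 0.03) and was not called without matching (percentile 24.5). Also open is whether weak narrow peaks come from few cells or from weak marking in many, which was not tested.

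Promoter peaks found in a single replicate may come from peak edges and from signal near the calling threshold. All 10 genes with a promoter peak in replicate 2 only and an enrichment of at least 10 had a replicate 1 peak within 1 kb outside the window (100%), but this does not decide the matter, since no replicate 2 peak of that enrichment lacked an overlapping replicate 1 peak and the outcome was nearly fixed. Over the 266 genes with a promoter peak in a single replicate, the median enrichment lay at percentile 1.26 of promoter peaks for replicate 2 and 0.742 for replicate 1. Low values were likely in advance, since peaks without any overlap were already known to be weak, so this does not settle the threshold explanation either. What stays open is the part of peak edges, that of the calling threshold and any difference between the animals pooled.

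Foxs1, Tek, Lum, Pecam1 and Acta2, genes of vessels and meninges, had a promoter peak in replicate 2 only, and no gene of these lists had one in replicate 1 only. More such cells in replicate 2 may be the reason. Of peaks found in a single replicate within 50 kb of any of the 28 genes of both lists, 69.2% were from replicate 2 against 50.6% elsewhere (36 of 52, unadjusted p = 0.00798, exact test), but neither list passed alone after adjustment over 25 lists (endothelial 0.767, mural 0.645), nor did both lists without peaks at promoters (27 of 42, p = 0.0892, exact test). Chance was not excluded (p = 0.168, exact binomial test), in a test that 5 genes are too few to pass, so either explanation stays open.

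No biological explanation could be tested between conditions, since the design has 1 group. The genes with the most distal peaks within 50 kb were Qk (19; 30 and 22 in the replicates), A830031A19Rik and Bcl11a (14 each), Btn2a2 and Cxxc5 (13 each), Btn1a1 and Pax2 (12 each), Pax3 and Zfp184 (11 each), and Nfix (11; 20 and 16 in the replicates). Of 269 families with at least 10 members, 88 had a higher and 54 a lower share of marked genes than other genes after adjustment over the families, 75 differed when stratified by CpG class, and 17 had no promoter peak. Breadth lay at or above percentile 97.5 in 41 families, where chance gives about 2.5%, and at or below percentile 2.5 in 10. Families whose random lists mostly had a median breadth of 0 could not reach the low side, so these counts cannot be compared. On the X chromosome 51.5% of 948 genes had a promoter peak and the median enrichment was 17.6, against 68.2% and 30.0 on autosomes. Animals of both sexes were pooled, and enrichment was not adjusted for the number of X copies. Within CpG-rich promoters the shares were 92.9 and 98.2%, and within the others 36.2 and 41.3%, and 255 genes of the X chromosome and 9822 of 20807 autosomal genes were CpG-rich.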
